A study of Mus musculus with 3 samples.

How the data were processed

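ChIP-seq libraries for REV-ERB alpha, REV-ERB beta and input were made from mouse liver at zeitgeber time 8. Per the labels' protocols, fixation had 2 steps: 30 minutes in disuccinimidyl glutarate at 2 mM, a crosslinker that joins proteins to each other, and 10 minutes in 1% formaldehyde, which fixes protein to DNA. Libraries followed a standard Illumina procedure. Per the submitters' processing notes, Bowtie and HOMER were used with the mm9 assembly; their versions, the read filters and the total number of tags per library are not given in the sources used here. Bowtie aligns short reads and HOMER calls peaks.

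The authors deposited 1 peak list per antibody, each from 1 library. Per the file headers, every peak has a fixed window, 153 bp for alpha and 210 bp for beta, and each list gives 4 raw tag counts: tags at unique positions in the window, all tags in the window, tags in 10000 bp around the peak, and input tags in the window. These deposited counts are not scaled to library size. The deposited peak score is a whole number that the authors' peak caller assigned, with a lowest value of 14 in the alpha list and 12 in the beta list. The deposited FDR (false discovery rate), a value from the authors' peak caller, is 0 in every row of both lists and was not used to rank peaks. Mean input at shared peaks was 1.35 times higher in the beta windows than in the alpha windows, against a ratio of window sizes of 1.37. The lowest ratio of tags to input tags was 4.70 in the alpha list and 4.13 in the beta list, where input was above 0. The smallest distance between peak centres was 384 bp in the alpha list and 528 bp in the beta list, so no peak overlapped more than 1 peak of the other list.

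The beta list as used here has no peak on chromosome 8. The comparison of the lists therefore covers 19 chromosomes. The overlap is given both as a share of the whole alpha list and without chromosome 8. Most alternative settings are given with the chromosome 8 peaks counted, as shares of the peaks that each setting keeps.

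Samples were grouped by the antibody named in the labels. Before the data were examined, the overlap rule, the rule for named sites and part of the alternatives were fixed. The alternatives without chromosome 8 or X, with centres within 500 bp, with a common lowest score, with unique positions and with density over background were chosen later, as were all settings for the clusters and for strong peaks without a partner. Peaks were shared if they overlapped by at least 1 bp (bedtools 2.31.1). Chance overlap was taken from 100 random placements of the beta peaks between the first and last peak of each chromosome. Shares have 95% Wilson intervals. The plan had assumed normalised tag counts and a fold over input as columns. The lists hold raw counts, so tags in the window were used. Ratios of alpha to beta were centred on their median over the shared peaks of each setting. Fold over input was computed as tags plus 1 over input tags plus 1. With 1 library per antibody, a size of 2-fold from the median stood in place of a test. Intervals of single ratios are exact (Clopper-Pearson) intervals of the alpha share of the tags of both libraries, so they compare these libraries and not the receptors in general. Tag density over background is the tags per bp in the window over the remaining tags per bp in the 10 kb around it.

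The sites named are the 10 shared peaks with the most tags in each list, the 5 highest peaks of each list without an overlapping peak in the other, and the 5 shared peaks above the median height with the most extreme ratio on each side; the alpha-only set leaves out chromosome 8. With mm9 sequence and gene annotation not used here, the planned comparisons of genomic location, of 16 gene lists and of 15 sequence motifs were not made, and sites are named by position.

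The alternatives were a stricter overlap, distances between centres of up to 100 or 500 bp, a ratio of tags to input of at least 8, the top 50% of each list, lists of equal length, a common lowest score, random placement within 50 kb, and other measures of height. The matching and the ratio rule were checked on simulated data: all 5000 shared sites of a simulated pair of lists were found. In those lists partners always overlapped and other sites lay far apart, so this was an easy case. With tag counts drawn for the 13314 real shared peaks and 200 of them changed 4-fold, 99.5% of the changed and 0.938% of the unchanged peaks passed the 2-fold rule for the ratio. The drawn counts had no repeated tags and no variation between libraries, so in real data more unchanged peaks may pass. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.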

Results

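Binding sites of REV-ERB alpha and REV-ERB beta were mapped in mouse liver by chromatin immunoprecipitation followed by sequencing (ChIP-seq). REV-ERB alpha and REV-ERB beta are nuclear receptors of the circadian clock that act as transcriptional repressors; they are encoded by the genes Nr1d1 and Nr1d2. Livers came from male C57BL/6 mice aged 20 weeks that had been kept for 3 days on a light/dark cycle of 12 hours each and were harvested at zeitgeber time 8, which is 8 hours after lights on. Each antibody was represented by 1 library, and 1 liver input library served as the control, so no value has a replicate error and no test between the receptors across animals was possible. The intervals given are 95% intervals that treat peaks or tags as independent and leave out variation between libraries. Sequenced tags that share a position need not be independent molecules, so the intervals of tag ratios may be too narrow even for counting error. Neighbouring peaks need not be independent either. The comparison implied by the design was which sites were occupied by both receptors and which by 1 of them. Positions are in the mm9 assembly. Peaks were not assigned to genes, because no mm9 gene annotation was used here.

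The REV-ERB alpha list held 24461 peaks and the REV-ERB beta list 22097. Together, the windows of the alpha peaks held 910669 tags and those of the beta peaks 1227074; total library depths are not given in the sources used here. The median alpha peak held 27.0 tags (quartiles 19.0 and 44.0) in a window of 153 bp, at 23.0 unique tag positions, against a mean of 2.66 input tags in the same window. The median beta peak held 39.0 tags (quartiles 25 and 66.0) in a wider window of 210 bp, at 25 unique positions, against a mean of 3.59 input tags. Tags per unique position had a median of 1.17 in the alpha list and 1.60 in the beta list, so part of the higher beta tag count consisted of repeated tags at the same position. The tag density of the median peak was 11 times that of the surrounding 10 kb in the alpha list and 12.3 times in the beta list. No peak of either list had a density below 4 times its surroundings. The lowest value was the same in both lists, so this floor may come from the peak calling and not from the binding.

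The autosomes carried most sites of both receptors. Chromosome 19 had the densest alpha binding, with 15.7 peaks per Mb, and chromosome 3 the sparsest among the autosomes, with 8.11. The X chromosome, of which male mice carry a single copy, had 193 alpha peaks and 255 beta peaks, and the alpha density there was 1.21 peaks per Mb. Mean input at the alpha peaks was 1.52 tags on the X chromosome and between 2.55 and 2.81 on the 19 autosomes. Beta peaks were 1.32 times as many as alpha peaks on the X chromosome, whereas the same ratio ranged from 0.871 to 1.01 over the 18 autosomes on which both lists had peaks. On chromosome 8 the alpha list had 1415 peaks and the beta list as used here had 0. All comparisons of the receptors below therefore rest on the other 19 chromosomes, unless the whole alpha list is named.

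**Figure D1:**
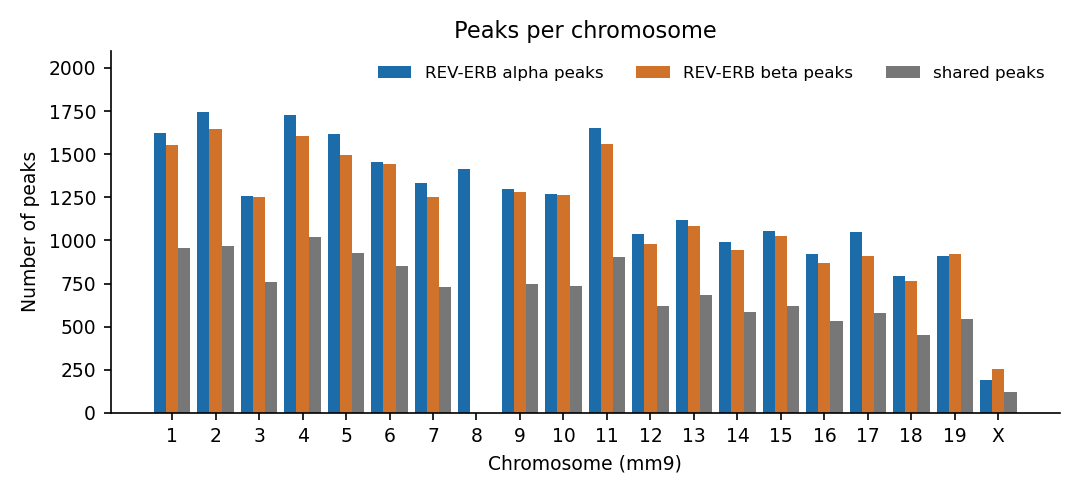
Number of peaks (vertical axis) on each mm9 chromosome (horizontal axis) for REV-ERB alpha, REV-ERB beta and the peaks shared by both. Chromosome 8 has 1415 alpha peaks and 0 beta peaks, and the X chromosome is the one with the highest number of beta peaks relative to alpha peaks (255 against 193).

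More than 1 in 2 peaks of each list coincided with a peak of the other (at least 1 bp of overlap). Recognition of 1 receptor by the antibody against the other was not tested. Shared peaks are therefore not shown to be bound by both receptors. The lists shared 13314 peaks. This was 57.8% of the 23046 alpha peaks outside chromosome 8 (Wilson interval 57.1% to 58.4%), 54.4% of the whole alpha list (53.8% to 55.1%) and 60.3% of the beta list (59.6% to 60.9%). The remaining 9732 alpha peaks outside chromosome 8 and 8783 beta peaks were found in 1 list only. When the beta peaks were placed at random on their own chromosomes, a mean of 82.4 alpha peaks was overlapped in 100 placements (range 61 to 107), so the observed number was 162 times the random mean. Moving each beta peak to a random place within 50 kb of its own position gave a mean of 357 overlaps (range 305 to 394). The shared fraction varied little between autosomes, from 54.5% to 60.7% of the alpha peaks. On the X chromosome 61.1% of the alpha peaks and 46.3% of the beta peaks were shared, against 57.9% to 63.5% of the beta peaks on the autosomes.

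The centres of shared peaks lay close together, in part because the rule of overlapping windows limits how far apart they can be. The distance to be found under this limit alone was not computed. The median distance between the centres of the alpha and beta peaks was 28.0 bp (quartiles 13.0 and 50 bp), and 10013 of the 13314 pairs (75.2%) lay within 50 bp. The median distance was 22.0 bp in the quartile of shared peaks with the most alpha tags and 33.0 bp in the quartile with the fewest. Requiring that the windows overlap by at least 50% of both peaks left 11794 shared peaks, or 48.2% of the whole alpha list, 51.2% of it without chromosome 8 and 53.4% of the beta list.

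Strong sites were shared far more often than weak ones. In the lowest decile of alpha peaks, which held 11 to 16 tags, 27.0% were shared (25.3% to 28.9%), and in the highest decile, with 70 to 456 tags, 89.6% were shared (88.3% to 90.8%). The share in the beta list went from 24.3% (22.5% to 26.1%) in the lowest decile, with 11 to 20 tags, to 95.6% (94.7% to 96.4%) in the highest, with 111 to 801 tags. Shared alpha peaks had a median of 35.0 tags (quartiles 24.0 and 56.0) and alpha peaks without an overlapping beta peak 20.0 tags (17.0 and 28.0). For beta the medians were 52.0 tags (33.0 and 86.0) and 27.0 tags (21.0 and 39.0). Among the peaks found in 1 list only, 1725 alpha peaks (17.7%) and 1361 beta peaks (15.5%) nevertheless had a peak centre of the other list within 1 kb. Each list has its own lowest score, 14 for alpha and 12 for beta, and a peak just below it is counted as absent.

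**Figure D2:**
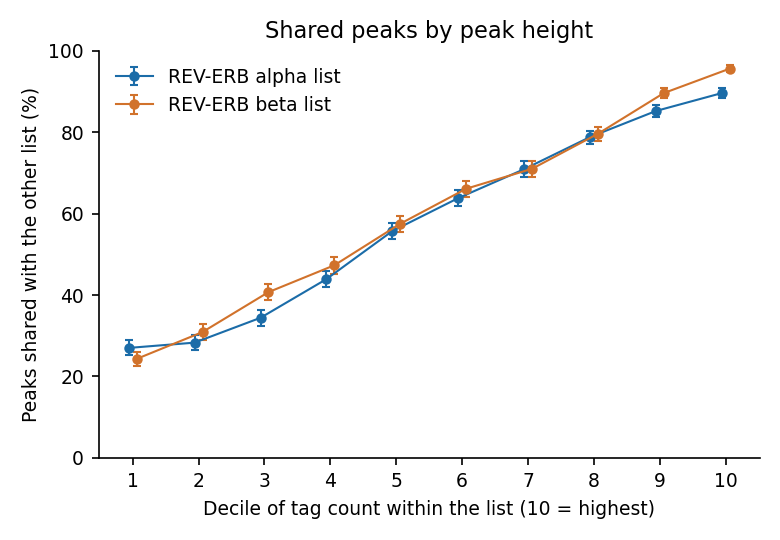
Percentage of peaks that overlap a peak of the other list (vertical axis) in each decile of tag count within a list (horizontal axis, 10 is the highest), without chromosome 8 for alpha; bars are 95% Wilson intervals. The share rises from 27.0% to 89.6% in the alpha list and from 24.3% to 95.6% in the beta list.

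The shared site with the most beta tags lay on chromosome 9 at 24316414 to 24316566 for alpha (405 tags, 4 input tags) and 24316397 to 24316607 for beta (801 tags, 4 input tags); it was the second among the shared peaks by alpha tags. Of the 10 shared peaks with the most alpha tags and the 10 with the most beta tags, 4 were in both sets. The other 3 of these lay on chromosome 1 at 90110291 to 90110443 (339 alpha and 588 beta tags), on chromosome 1 at 90184770 to 90184922 (336 and 592 tags) and on chromosome 13 at 52861730 to 52861882 (306 and 500 tags). Both chromosome 1 sites also had high input, with 35 and 25 input tags in the alpha windows. A further 6 sites completed the alpha set. The site with the most alpha tags was on chromosome 11 at 7052552 to 7052704 and held 452 alpha and 163 beta tags. A second site on chromosome 11, at 109356267 to 109356419, held 404 alpha and 450 beta tags, and the third, at 100454120 to 100454272, held 350 and 287. The site on chromosome 3 at 51037526 to 51037678 held 376 alpha and 356 beta tags, that on chromosome 19 at 36709419 to 36709571 held 375 and 384, and that on chromosome 2 at 29478845 to 29478997 held 304 and 198. Among the sites that completed the beta set, chromosome 7 at 54001270 to 54001480 held 675 beta and 279 alpha tags. Chromosome 12 at 33996707 to 33996917 held 626 beta and 162 alpha tags, and chromosome 1 at 132575251 to 132575461 held 531 and 102. Chromosome 2 at 132697627 to 132697837 held 516 beta and 201 alpha tags, chromosome 14 at 69891802 to 69892012 held 512 and 203, and chromosome 17 at 80337671 to 80337881 held 499 and 186.

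At shared sites the tag counts of the 2 libraries were correlated, and most sites had a ratio close to the median. Across the 13314 shared peaks, log2 tag counts had a Pearson r of 0.66 (0.65 to 0.67, treating peaks as independent, which they are not) and a Spearman rho of 0.63. The alpha count was 0.688 times the beta count at the median, and 0.944 times with unique tag positions. The ratio of tags mixes library depth, window size, repeated tags at the same position and binding, so each ratio was set against its median. On that scale 10903 shared peaks (81.9%) lay within 2-fold of the median, 1118 (8.40%) were at least 2-fold higher in alpha and 1293 (9.71%) at least 2-fold higher in beta. Counting error alone gave means of 38.5 and 65.1 such peaks in 100 simulated draws, with highest values of 57 and 86. These draws leave out the variation between libraries, which a single library per antibody does not show. With unique tag positions in place of tags, a measure chosen after the data were seen, 869 peaks were higher in alpha and 1017 in beta, against simulated means of 107 and 111. With tags over input tags, 1839 were higher in alpha and 1761 in beta. Among the 6652 shared peaks above the median height (the geometric mean of both tag counts), Pearson r was 0.38 (0.36 to 0.40) and Spearman rho 0.32. Around the median ratio of these peaks, 0.629, 672 peaks were higher in alpha and 599 in beta. The direction of the small excess thus depended on the setting. The centre of 0.629 lay below the 0.688 of all shared peaks, so part of this change may come from the centre. A selection on height narrows the range of counts, which lowers a correlation; how much of the drop it accounts for was not measured.

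**Figure D3:**
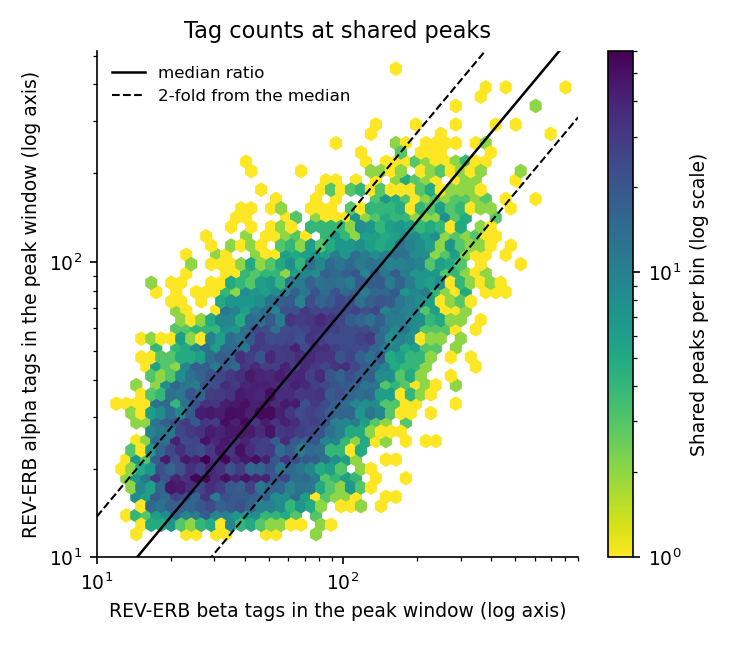
REV-ERB alpha tags (vertical log axis) against REV-ERB beta tags (horizontal log axis) at the 13314 shared peaks, coloured by the number of peaks per bin; the solid line is the median ratio of 0.688 and the dashed lines are 2-fold to either side. Most peaks (81.9%) lie between the dashed lines.

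The shared sites that leaned most to alpha, among those above the median height, were led by chromosome 18 at 35974427 to 35974579, with 214 alpha and 39 beta tags, a ratio 7.98-fold above the median (log2 3.00, exact interval 2.5 to 3.53). It was followed by chromosome 3 at 129582198 to 129582350, with 203 alpha and 43 beta tags (log2 2.78, 2.30 to 3.29), and chromosome 5 at 137923258 to 137923410, with 104 and 23 tags (log2 2.72, 2.06 to 3.44). Chromosome 10 at 12363188 to 12363340 held 120 alpha and 29 beta tags, and chromosome 11 at 18918970 to 18919122 held 153 and 37. The site that leaned most to beta was on chromosome 1 at 163906536 to 163906746, with 171 beta and 16 alpha tags, a ratio 7.35-fold below the median (log2 -2.88, -3.72 to -2.14). Next came chromosome 11 at 21449948 to 21450158, with 155 beta and 16 alpha tags (log2 -2.74, -3.58 to -1.99). On chromosome 3, 3 sites followed, at 148768266 to 148768476 (181 beta and 19 alpha tags), 63144464 to 63144674 (142 and 15) and 120889883 to 120890093 (231 and 25). All 10 intervals excluded the median ratio, but they treat every tag as independent and leave out variation between libraries. These sites were also picked for their extreme ratios.

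The 5 strongest sites found in 1 list only lay farther from peaks of the other list for alpha than for beta. The highest peak of the whole alpha list had no overlapping beta peak: it lay on chromosome 10 at 80755897 to 80756049, with 456 tags against 12 input tags, and the nearest beta peak centre was 3236 bp away. The next 4 alpha-only peaks were farther from any beta peak. They lay on chromosome 7 at 148414415 to 148414567 (423 tags, nearest beta centre at 12066 bp), chromosome 13 at 54795257 to 54795409 (369 tags, 29234 bp), chromosome 11 at 59623358 to 59623510 (324 tags, 22942 bp) and chromosome 5 at 121062714 to 121062866 (284 tags, 25898 bp). The strongest beta-only peaks stood close to alpha peaks. They lay on chromosome 4 at 62893781 to 62893991 (318 tags, nearest alpha centre at 1520 bp), chromosome 6 at 71123196 to 71123406 (240 tags, 219 bp), chromosome 1 at 186648606 to 186648816 (235 tags, 273 bp), chromosome 12 at 16637273 to 16637483 (224 tags, 241 bp) and chromosome 2 at 172978113 to 172978323 (223 tags, 720 bp). In rank, the 5 alpha-only peaks stood at 1, 3, 8, 12 and 18 of the alpha list, and the 5 beta-only peaks at 88, 271, 289, 339 and 346 of the beta list. The tag counts of the other receptor at single-list sites were not measured here, so these peaks are absent from a list and not shown to be unoccupied.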

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

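The alpha list had 1415 peaks on chromosome 8 (5.78% of the list) that entered no comparison with beta, because the beta list as used here held 0 peaks there. This signal outside the comparison was like that on the other chromosomes: the median was 28.0 tags against 27.0 elsewhere, and the mean input was 2.68 tags. The strongest of these peaks lay at 95758009 to 95758161, with 240 tags and 0 input tags. No group had enough samples to look for an outlying library.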

How the results depend on the processing

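The overlap moved with the rule under the 8 alternatives run, some of which shorten the lists. Of the alpha peaks kept by each, between 48.2% and 58.6% were shared (51.2% and 62.4% without chromosome 8). Of the beta peaks kept, between 53.4% and 65.0% were shared. As shares of the whole alpha list and the beta list, it was 48.2% and 53.4% with 50% of both peaks overlapping. With centres within 100 bp, it was 51.3% and 56.8%. With tags at least 8 times the input, it was 52.3% of 17967 alpha peaks and 57.7% of 16304 beta peaks. In the top 50% of each list, it was 58.6% of 12231 alpha peaks and 64.8% of 11049 beta peaks. At equal length, it was 57.7% of 22097 peaks in both. A further 3 alternatives were chosen after the data were seen. The overlap was 57.8% of the alpha list without chromosome 8, and 58.0% and 63.3% with centres within 500 bp. With the alpha list's lowest score in both lists, it was 52.1% of the alpha list and 65.0% of the 19594 beta peaks kept. Random placement within 50 kb raised the chance overlap from 82.4 to 357 peaks; neither placement models open chromatin or the common input, so part of the excess over chance may come from these. The Pearson r of 0.66 became 0.63 with fold over input and 0.38 above the median height, where selection narrows the range of counts, and, chosen after the data were seen, 0.67 with unique positions and 0.69 with density over background. Peaks at least 2-fold higher in alpha numbered 1839 with fold over input; above the median height, with 6652 peaks tested, 672 were higher in alpha and 599 in beta. In these 2 settings more peaks leaned to alpha than to beta, the opposite of the main counts of 1118 and 1293. Each setting was centred on its own median ratio. Above the median height this was 0.629 in place of 0.688, so that reversal may come in part from the moved centre. The ratio of median tags in shared to single-list alpha peaks was 1.67 over the whole alpha list, with all chromosome 8 peaks counted as single-list. It was 1.76 with 50% overlap on the same basis and, chosen after the data were seen, 1.75 without chromosome 8. The alternatives for genomic location, gene lists and motifs, and the ratio scaled to library totals, were not run, since they need mm9 sequence or annotation or the library totals. No paired analysis was possible because each antibody had 1 library, which also leaves no library to leave out. Peaks at the lowest score held 11 to 25 tags in the alpha list and 11 to 31 in the beta list; the effect of depth was not tested.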

Other observations

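The clusters, the tests of strong alpha sites and the test of X background were chosen after their values had been seen; the random draws for X and the ratio less background on X were set down before. Outside chromosome 8, which was left out of the cluster counts, REV-ERB alpha peaks lay closer together than peaks placed at random. When peaks whose centres were at most 10 kb apart were chained, 58.4% were in chains of at least 2 peaks, against a mean of 18.5% (range 17.6% to 19.2%) in 100 placements across the chromosomes and 46.0% (45.2% to 46.7%) in 100 placements within 50 kb of each peak's own position. Much of the excess over placement across the chromosomes was thus also present in placements that kept the density of peaks at a wider scale, and neither placement models open chromatin. With a cutoff of at least 8 peaks, also chosen after the values were seen, there were 63 clusters with 598 peaks, against a mean of 30.1 (18 to 45) in placements within 50 kb. The cluster with the most peaks outside chromosome 8 lay on chromosome 14 at 26270759 to 26329205 and held 18 alpha and 14 beta peaks, of which 14 were shared. The next lay on chromosome 5 at 66435261 to 66505710, with 17 alpha and 15 beta peaks, and on chromosome 5 at 125766471 to 125821392, with 16 and 11. Chromosome 9 at 69132885 to 69187339 held 14 alpha and 11 beta peaks, and chromosome 11 at 100671960 to 100720833 held 14 and 7. The cluster on chromosome 14 had a mean of 4.33 input tags, against 2.69 to 3.00 in the other named clusters. Over the alpha list the mean was 2.66. Alpha peaks in clusters were shared at 61.7% (57.7% to 65.5%) and other alpha peaks at 57.7% (57.0% to 58.3%), intervals that overlap.

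The strongest alpha sites included a group with no beta peak nearby that had no equally large counterpart in the beta list. Of the 2304 peaks in the top decile of the alpha list, 115 (4.99%, 4.17% to 5.96%) had no beta peak centre within 5 kb. In the top decile of the beta list, 20 of 2209 peaks (0.905%, 0.587% to 1.39%) had no alpha centre that near. These top deciles were cut slightly differently from the highest deciles given earlier, which held 2305 alpha and 2210 beta peaks. The alpha count was 114 with ranking by unique positions, 153 at 1 kb, 75 at 20 kb and 75 of 2101 among peaks with at most 5 input tags, where the beta counts were 25, 47, 6 and 12 of 1777. Ranking by density over background brought the lists closer, at 371 (16.1%, 14.7% to 17.7%) and 286 (12.9%, 11.6% to 14.4%). These 115 peaks had fewer neighbours: a median of 2 other alpha peaks lay within 50 kb, against 5 for shared peaks of the top decile. Their windows held a median of 38.9% of the tags in the surrounding 10 kb, against 27.7%. Peak width was not measured. Both differences may come in part from the selection. A peak with alpha neighbours within 5 kb could often have a beta centre there and so not be counted.

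Repeated amplification is argued against by tags per unique position, which differed from shared alpha peaks within 10% of the same height by a median of 0.0055 (quartiles -0.0354 and 0.0586). Signal in the input is argued against as the whole cause: among peaks with at most 5 input tags, 3.57% (2.86% to 4.45%) of the top alpha peaks still lacked a partner, against 0.675% (0.387% to 1.18%) of the top beta peaks. The cap is stricter in the wider beta windows, but without a cap the beta share was 0.905% (0.587% to 1.39%). Input remains open as a part of the cause. The peaks without a partner had a median of 5 input tags, against 3 in shared top-decile peaks. Against shared peaks of like height, tags over input (after adding 1 to each) differed by a median of -5.83 (quartiles -11.6 and 8.41). They were higher in only 37 of 114 matched peaks. List thresholds remain open, because beta tags at these sites were not measured here; 23 of the 2063 shared top-decile alpha peaks had a beta peak of at most 31 tags, the highest count seen at the lowest beta score. Binding by REV-ERB alpha alone and recognition of another protein by the alpha antibody both remain open as hypotheses; receptor and antibody are the same factor in this design, and neither was tested.

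Shared peaks on the X chromosome leaned to beta. The median log2 ratio of alpha to beta at 118 shared X peaks was -0.27 relative to the autosomes, whose own medians ranged from -0.078 to 0.081, and 0 of 10000 draws of as many autosomal peaks of like height had a median as low (the lowest was -0.20). The background in the 10 kb around these peaks was shifted too. Its median ratio on X was -0.27, below the autosomal range of -0.13 to 0.16. The lower minimum score of the beta list stays open as a cause, because this background was not free of selection. Every listed peak had at least 4 times the tag density of its surroundings. A difference in tag coverage along the whole chromosome is a candidate explanation. The peak ratio less the background ratio on X was 0.0027, inside the autosomal range of -0.12 to 0.09. This background was taken only around shared peaks and can hold their flanks and neighbouring peaks. It may therefore follow the peak ratio in part, and coverage farther from the peaks was not examined. Base composition was not tested, no biological explanation was tested, and the excess of beta peaks on X (255 against 193) stays open on the same grounds.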
